A study of Bombyx mori with 8 samples.

How the data were processed

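The series holds 8 single-colour Agilent arrays of Bombyx mori larval midgut, 2 for each of 4 groups: Sarupat and CSR-2, each uninfected and 12 h after oral BmNPV. Per the labels, each race had 3 replications of 25 silkworms, RNA was taken with RNeasy columns, and 500 ng of total RNA per array was primed with oligo-dT and labelled with Cy3. The labels do not say which replication or how many larvae each array holds, or when the uninfected larvae were sampled. Samples were grouped by the race and infection that the labels give.

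The deposited scanner files hold intensity values for each spot, which the authors obtained with Agilent Feature Extraction 11.5.1.1 per the file headers: a processed signal that is background-subtracted and detrended, the raw mean signal, the local background, and flags for spots well above background, saturated or irregular. The deposited value table holds log2 values, which the authors scaled per array in a way that is not stated. Checked against the scanner files, its 34230 probes have a 75th percentile near 0 and a slope near 1 on the log2 processed signal of each array, and genes are not centred. Its medians are -4.09, -3.93, -3.94 and -3.91 on the Sarupat arrays and -3.43, -2.56, -3.32 and -3.09 on the CSR-2 arrays. The scanner files were used, with the value table as an alternative. File headers place Sarupat on 1 slide, scanned once, and CSR-2 on another, scanned in 2 runs, uninfected and infected apart. The detector voltage was 469 for Sarupat, 377 for uninfected and 472 for infected CSR-2 arrays.

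Each array carried 34237 probes, 9566 of them on 2 spots, for 27419 gene identifiers, and 13918 identifiers have a product name. Names are those of the array's annotation. Only 41 identifiers matched the supplied table of RefSeq accessions of assembly ASM3026992v2, and 121 have the form of a RefSeq accession, so no positions were added. Product names describe best matches, and many identifiers share 1 name. The array design marks 12259 probes as cross-hybridising. Duplicate spots were averaged on the log2 scale, and a gene with several probes was represented by its brightest. A gene was kept when a probe of it was well above background on both arrays of at least 1 group, which left 16104 genes.

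The log2 processed signal of each array was shifted by its 75th percentile. That percentile was taken over the 8589 probes well above background on all 8 arrays, since on the CSR-2 arrays most probes are not detected and the percentile over all probes falls among dim spots. The percentile over all probes, as first planned, is an alternative. Before any comparison, the spread between the arrays of a group was set against that between duplicate spots. The arrays of infected Sarupat larvae differed by 0.123 (SD, log2), less than duplicate spots did (0.138 and 0.131), so they were averaged and counted as 1 sample. The SD between arrays was 0.398 for uninfected Sarupat, 0.708 for uninfected CSR-2 and 0.169 for infected CSR-2 larvae. The fit of 7 samples has 3 residual degrees of freedom and assumes that the lone infected Sarupat sample varies like the other groups. Results with 8 arrays as samples, as first planned, are given beside it. So are those with 6 samples, in which the infected CSR-2 arrays also count as 1. Apart from these 2 changes (the probes of the percentile and the samples counted), the comparisons, tests, gene lists, rule for named genes and main alternatives were fixed before the data were examined.

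Comparisons used limma 3.58.1 in R 4.3.3, with 4 group means and moderated variances, and Benjamini-Hochberg adjusted p under 0.05. There were 5: infection in each race, the difference between these effects, and the race difference in uninfected and in infected larvae. The 31 gene lists were defined by patterns in product names, so some members are of another kind: 37 inhibitors and molting fluid enzymes among 168 digestive proteases, 23 transposon and other names among 57 virus genes, 10 vacuolar subunits in mitochondrial respiration, and 5 fibrohexamerin genes in both the fat body and silk gland lists. They were tested with camera (preset correlation of 0.01, then estimated) and with fry, adjusted over the lists of a comparison. The estimated correlation rests on 3 residual degrees of freedom, so a list not called with it is not shown to be unshifted. Of the 31 lists, camera with the preset correlation called 5 in Sarupat, 11 in CSR-2, 9 for the difference between the effects, 6 for uninfected and 4 for infected larvae. With the estimated correlation camera called 0 in each, and fry, which tests whether a list moves on balance 1 way, called 0, 7, 0, 0 and 2. The fry calls in CSR-2 were the antimicrobial, autophagy, heat shock, sugar, glycolysis, proteasome and aminoacyl-tRNA synthetase lists. Lists of other cell types (hemocyte, muscle, fat body, silk gland, Malpighian tubule, neural) were included as possible parts of a midgut sample. Named genes were, for each infection comparison, the 10 largest rises and 10 largest falls among changed genes with a product name whose infected arrays all lay on 1 side of the uninfected ones. For the other comparisons they were the 5 largest each way, and in each list up to 4 members with the smallest p. All measured BmNPV genes are named in the plot of their levels. Genes with unnamed products were counted but not named.

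A fold was given as measured when both groups were above background and unsaturated. When 1 group was below background on its arrays, its level was set to at least the lowest signal called well above background on each array, and the fold is a bound ("at least"). When both groups were below background no fold was given. A group above background on 1 of its 2 arrays counted as above it in the counts (803 genes in Sarupat and 1365 in CSR-2, of which 0 and 305 changed). For named genes of this kind with a change the dim array was set to its floor and the fold given as a bound. A difference between the infection effects was given as measured only when all arrays were above background, and otherwise as a bound or without a size. These floors were -9.51, -9.20, -9.35 and -9.19 (log2, shifted) on the Sarupat arrays and -5.97, -5.06, -5.96 and -5.82 on the CSR-2 arrays, so low levels that Sarupat arrays show go undetected on CSR-2 arrays. The fit and the list test were tested on simulated data of the same design with 200 changed genes of 16104. Each simulated gene had the same spread in all groups and genes varied independently. The unequal spread of the groups in the data was therefore not tested. In Sarupat the fit recovered 0% at a log2 size of 1, 28.4% at 2 and 97.0% at 4, with 15 false calls. In CSR-2 it recovered 0%, 64.2% and 100%, with 8 false calls.

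Alternatives were median centring, quantile normalization, normexp background correction (offset 50) with the percentile shift or with quantile normalization, filters on dim probes, means over probes or each probe alone, a replicate block, trend and robust or unmoderated variances, fold thresholds of 2, only the arrays compared, array weights, the deposited value table, and each array left out. The first plan, 8 arrays as samples and the percentile over all probes, was kept as an alternative, each part alone and both together. After the data were seen, 7 were added: 6 samples, scaling to 4 E1A spike-ins, cyclic loess, genes above background in a compared group, and leaving out cross-hybridising probes, repeated product names (over 20 genes) or list members with names of another kind. Smooth curves were fitted with mgcv 1.9.3. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the files, ran permutations and drew the plots. No sample was left out.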

Results

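Gene expression was measured in the midgut of fifth-instar larvae of 2 Indian silkworm races, Sarupat and CSR-2, on 8 single-colour arrays. Per the labels, Sarupat is resistant and CSR-2 susceptible to Bombyx mori nucleopolyhedrovirus (BmNPV), a baculovirus that larvae take up by mouth and that enters through the midgut. Each race had 2 arrays of uninfected larvae and 2 arrays of larvae collected 12 h after they were fed 40000 polyhedral inclusion bodies, the occluded form of the virus. The labels do not give the sampling time of the uninfected larvae. Each array held 43803 non-control spots for 27419 gene identifiers, of which 16104 were measured well enough to test. The share of spots well above background was 56.7%, 56.2%, 57.5% and 56.7% on the Sarupat arrays (uninfected, then infected). It was 30.6%, 25.5%, 33.9% and 32.3% on the CSR-2 arrays in the same order. The number of arrays limits the precision of every value below. The 2 arrays of infected Sarupat larvae differed by an SD of 0.123 (log2) per spot, less than duplicate spots on the same array (0.138 and 0.131), and were counted as 1 sample, which leaves 7 samples. Whether the arrays of the other groups held separate animals is not stated, so the p-values may measure only the spread between arrays and not that between animals. Positions in the genome are not given, because the array files list each probe as unmapped.

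The first comparison asked how the race labelled resistant responded to the virus (1 infected sample against 2 uninfected samples). Probes of BmNPV genes read higher after infection in Sarupat: all 29 BmNPV genes measured had a higher signal in infected larvae, and in 27 of them both infected arrays lay above both uninfected arrays. Of the 29, 28 were above background on both infected Sarupat arrays. A gene could pass the filter through these arrays alone, so part of the rise can follow from the filter. Their median log2 fold change was 1.66, from 0.26 for FP25 to 3.38 for FGF. The median was 1.13 with a normexp background correction before the percentile shift, which moved the median of all genes by 0.48, and 0.11 with normexp and quantile normalization. With no filter on dim probes it was 0.70 over 69 BmNPV genes, of which 53 were higher and 16 lower in infected larvae. The signal was 3.73-fold for P6.9, the DNA-packing protein of the virion (log2 fold change 1.90, SE 0.44, adjusted p = 0.446), and 4.21-fold for 39K, an early gene product (2.07, SE 0.62). Signal of DNAHel, the viral helicase, was at least 2.64-fold (3.15, SE 0.54). It was at least 3.40-fold for the DNA-binding protein DBP and 3.89-fold for the viral ubiquitin. VP39, the major capsid protein, had a log2 fold change of 1.45, and V-Cath, the viral cathepsin, 0.40. With limma, 0 BmNPV genes passed over all genes (1 with 8 arrays counted as samples), and 21 rose when adjusted over the list alone. Camera with its preset correlation called them shifted up as a set against other genes, and this was lost with a correlation estimated from the data (p = 0.0610 with an estimated correlation). In uninfected Sarupat larvae, 17 of the 29 genes were already above background on both arrays, so the probes also read signal in larvae not given the virus.

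**Figure D1:**
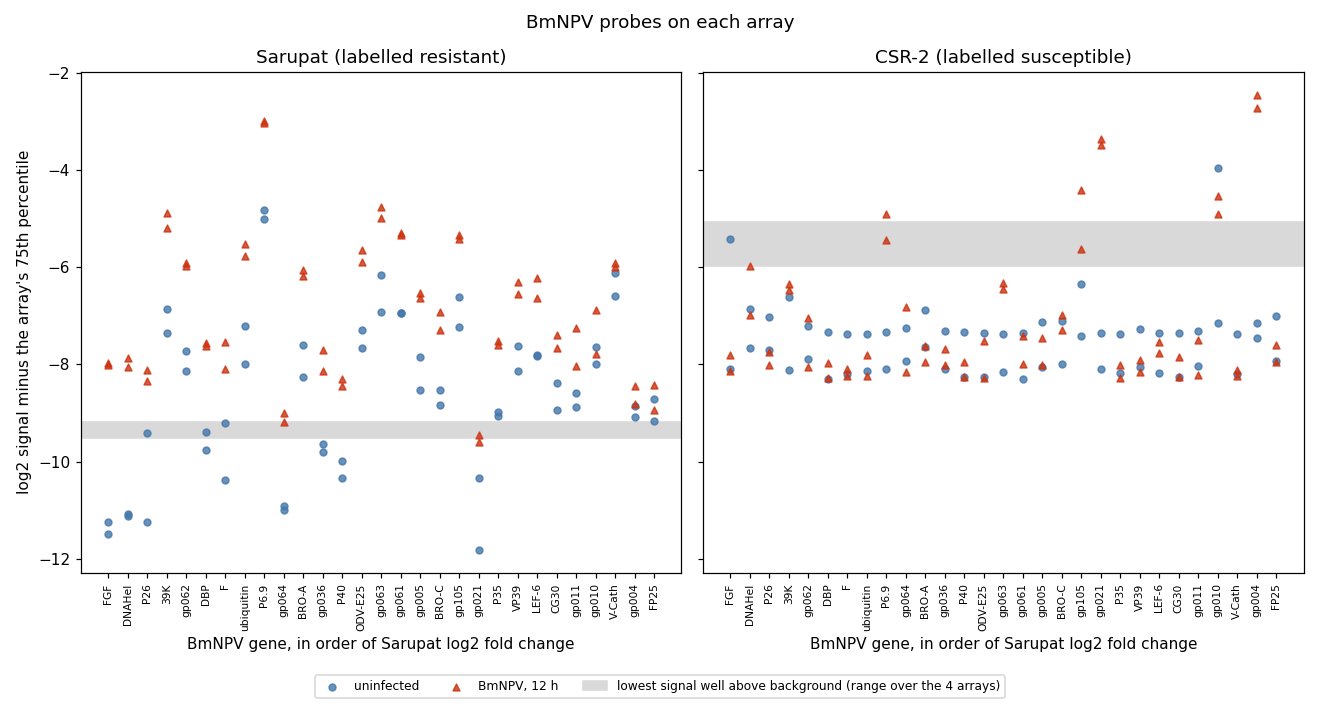
Signal of the 29 measured BmNPV genes on each of the 8 arrays, as log2 signal minus the array's 75th percentile, with circles for uninfected larvae and triangles for larvae 12 h after BmNPV. All 29 genes are higher in infected Sarupat larvae (median log2 fold change 1.66), while 24 lie below background on both infected CSR-2 arrays, whose detection floor (grey band) is higher than that of the Sarupat arrays.

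Among all genes, 15 changed in Sarupat, 9 up and 6 down. The split was 6 up and 0 down with the percentile over all probes and with the deposited values, while 97.6% of 5717 changed genes rose with normexp and the percentile shift. The fit as planned before the data were examined, with 8 arrays as samples and the percentile over all probes, gave 77 up and 30 down. A vacuolar protein sorting-associated protein 35 gene, Gene011781, part of the retromer that sorts membrane proteins, rose at least 76.1-fold (fitted log2 fold change 8.0, SE 0.44, adjusted p = 0.00802). A glycoside hydrolase, Gene011771, rose at least 69.9-fold (7.40, SE 0.50, adjusted p = 0.0119). Carboxypeptidase E, Gene012585, which trims peptides, rose at least 37.9-fold (6.62, SE 0.66). The reverse transcriptase Gene015014 rose 39.6-fold, measured in both groups (5.31, SE 0.37). The tyrosine-protein kinase receptor Gene007330 rose at least 4.64-fold and the cytochrome P450 Gene009225 at least 3.63-fold. A 26S proteasome regulatory ATPase, Gene014827, fell at least 36.4-fold (fitted log2 fold change -7.42, SE 0.64, adjusted p = 0.0327). The small heat shock protein Hsp20.8, Gene015286, a chaperone, fell 28.8-fold (-4.85, SE 0.46), but with 8 arrays counted as samples its adjusted p was 0.483 by limma. The fold change was the same in that fit, which adds the spread between the 2 infected arrays. These arrays therefore differed widely for this gene, and the SE given leaves that spread out. CYP6AE7, Gene009798, a cytochrome P450, fell at least 8.66-fold (-4.59, SE 0.43). The CCR4-NOT subunit eGene18433 fell at least 9.40-fold and the transcription factor IIIA eGene19889 at least 6.10-fold. With normexp and the percentile shift the fitted log2 fold changes of these last 3 genes were 0.14, 0.05 and 0.43, against a median of all genes of 0.48.

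Few members of the other lists passed in Sarupat. With 8 arrays counted as samples, 2 of 37 antimicrobial genes rose, cecropin A Gene016648 among them. The values that follow are for 7 samples. With limma, 0 of 37 antimicrobial peptide and lysozyme genes passed, and 5 had an unadjusted p under 0.05. Lysozyme Gene007002 had a log2 fold change of 2.03 (SE 0.40, adjusted p = 0.357) and cecropin A Gene016648, above background on 1 of 2 uninfected arrays, one of 1.85 (SE 0.40, adjusted p = 0.446). Of 107 heat shock and chaperone genes, 1 fell, and the list as a whole lay lower than other genes (median log2 fold change -0.25, camera adjusted p = 0.000417, but adjusted p = 0.707 with an estimated correlation). The members nearest to passing after Hsp20.8 were 2 genes for the 90-kDa heat shock protein, Gene015381 at -2.45 and Gene015380 at -2.33. Muscle markers, which come from the muscle around the gut, lay higher (median 0.34 over 38 genes, adjusted p = 0.00189, but adjusted p = 0.707 with an estimated correlation), for example the muscle M-line protein unc-89 Gene002430 at 0.93 and BMKETTIN Gene000218 at 0.79. None of these muscle genes passed singly. Peritrophic matrix and chitin genes lay higher (median 0.35 over 348 genes, adjusted p = 9.35e-08, but adjusted p = 0.707 with an estimated correlation). However, 309 of these carry 1 product name, peritrophin type-A domain protein 2, and without repeated names the median difference from other genes was -0.06. Cuticle proteins lay lower (median -0.18 over 137 genes, adjusted p = 0.0207, but adjusted p = 0.707 with an estimated correlation). Relative to other genes their median was -0.16, and with normexp and the percentile shift it was 0.14 and did not pass (adjusted p = 0.781). A list of 57 genes whose product names mention a virus or a virus protein lay higher (adjusted p = 2.36e-09, but adjusted p = 0.707 with an estimated correlation), with 20 up and 2 down adjusted over the list alone. Of its members 29 are the BmNPV genes, and 23 carry names of transposons, inclusion-type proteins or an apoptosis-associated factor. No other list was shifted as a set. Single members passed among protease names (1 rose), detoxification enzymes (1 rose, 1 fell), proteasome and ubiquitin genes (1 fell) and transposable elements (1 rose).

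The remaining lists in Sarupat had 0 members past the limma test, against 15 of all genes. Together with the antimicrobial list they hold 956 genes, of which 54 had an unadjusted p under 0.05, where chance gives 47.8. Over all 16104 genes 783 did, where chance gives 805.2. The remaining lists were microbial pattern recognition, Toll, Imd and JAK/STAT signalling, small RNA machinery, apoptosis, autophagy, serpins, lipases, carbohydrate digestion and antioxidant genes. To these came ecdysone and juvenile hormone, ribosomal proteins, mitochondrial respiration, glycolysis, vacuolar ATPase, DNA replication and aminoacyl-tRNA synthetases. Silk gland, fat body, hemocyte, Malpighian tubule and neural markers were the last. The pooled count hides differences between lists. By unadjusted p, the antimicrobial, pattern recognition, silk gland and carbohydrate digestion lists lay above chance and ribosomal proteins below it. In DNA replication, DNA polymerase epsilon subunit B, Gene015503, had a fitted log2 fold change of 4.63 (SE 0.59, adjusted p = 0.0848) and was the 1 member up adjusted over the list alone. Of the 15 changes, 13 rest on a bound because 1 group was below background. The count of 15 was 138 with 8 arrays counted as samples, 0 without either uninfected CSR-2 array, 49 without the first and 28 without the second uninfected Sarupat array. On simulated arrays of this design, 0 of 67 genes changed by a log2 of 1 were recovered, 19 of 67 changed by 2 and 64 of 66 changed by 4, and 15 unchanged genes were called as well. The 15 changes in the data can therefore hold false calls.

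The second comparison asked how the race labelled susceptible responded (2 infected against 2 uninfected arrays). In CSR-2, 11 of 37 antimicrobial genes rose and 0 fell. Falls outnumbered rises among heat shock proteins (30 against 5 of 107), sugar digestion and transport (17 against 4 of 65) and central metabolism (11 against 3 of 30). As sets these 4 lists passed with camera's preset correlation but not with an estimated one (adjusted p = 0.437). BTL-LP1, a bacteriophage T7 lysozyme-like protein (Gene009543), rose at least 169-fold (fitted log2 fold change 7.59, SE 0.29, adjusted p = 0.00151), with 1 of 2 uninfected arrays below background. Attacin Gene003697, an antibacterial protein, rose at least 13.1-fold (4.42, SE 0.33). Cecropin A Gene016648, a membrane-lysing peptide, rose at least 3.50-fold (3.19, SE 0.32) and lebocin-3 AK383348 at least 1.96-fold (3.21, SE 0.34). The small heat shock protein hsp20.1 fell 38.8-fold at Gene016763 (-5.28, SE 0.35, adjusted p = 0.00292) and 34.8-fold at Gene016764.

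In all, 3531 genes changed in CSR-2, 2004 up and 1527 down, and 3118 of them had a measured fold or a bound. In 305 of the changed genes a group was above background on only 1 of its 2 arrays, and named genes of this kind are given as bounds. Of the largest rises, peritrophin type-A domain protein 2 at E_ET_caL-_07G24_R_0, a protein of the gut's chitin lining, rose 67.4-fold (6.07, SE 0.70). Notch Gene008472, a cell-fate receptor, rose at least 29.6-fold (5.31, SE 0.65), the olfactory receptor Gene012905 at least 8.95-fold (5.07, SE 0.32) and the ionotropic glutamate receptor Gene013178 at least 8.86-fold (5.34, SE 0.39). The calcium channel subunit Gene002935 rose at least 9.39-fold and the dual specificity phosphatase eGene21207 at least 12.2-fold. Retroelements in this group were the reverse transcriptase-like gene eGene22373, up at least 24.0-fold at 1 of its 2 probes (6.68, SE 0.35) and at -0.58 at the other, the R1Bmks retrotransposon eGene22817, up at least 25.1-fold, and an endonuclease-reverse transcriptase, up at least 27.5-fold. Of the largest falls, vanin-like protein Gene015461 fell 82.8-fold (-6.37, SE 0.32, adjusted p = 0.0024). Arylphorin Gene001347, a storage protein of the fat body, fell at least 12.4-fold (-5.85, SE 1.34). The UDP-glucosyltransferase Gene004027, a detoxification enzyme, fell 32.9-fold (-5.04, SE 0.37) and the zinc/iron transporter Gene014534 fell 25.5-fold (-4.67, SE 0.38). Chymotrypsin inhibitor CI-b1 Gene000960 fell at least 9.93-fold and serine protease 39 Gene003761 at least 5.42-fold. The heat shock protein hsp23.7 fell 24.0-fold at Gene015402 and 22.5-fold at Gene015403. Probes of both hsp23.7 and both hsp20.1 genes are marked as cross-hybridising, so the 2 falls of each name may not be independent. Those of Gene015461, Gene000960, eGene22817 and the endonuclease-reverse transcriptase above are marked as well.

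By list, antimicrobial peptides and lysozymes had 11 of 37 members up and 0 down (16 up adjusted over the list alone), the others not passing. The list was shifted up as a set (median log2 fold change 0.62, camera adjusted p = 0.000984, but adjusted p = 0.437 with an estimated correlation). Of all 16104 genes, 2004 rose and 1527 fell in CSR-2. Hemocyte markers were shifted up as a set (median 0.46, camera adjusted p = 0.0392, but adjusted p = 0.437 with an estimated correlation). Of these 40 markers 3 rose, a smaller share than of all genes, and 0 fell. The 3 were alpha integrin U76605.1 (at least 6.98-fold), paralytic peptide binding protein 2 Gene013684 (at least 1.25-fold) and the prophenoloxidase-activating proteinase Gene015619 (2.95-fold). Of the 40 hemocyte markers, 17 were above background in uninfected CSR-2 midgut and 5 are in another list too. Pattern recognition genes had 5 of 27 up and 3 down, led by a beta-1,3-glucan-binding protein, Gene006415 (25.1-fold, 4.65, SE 0.58). Toll, Imd and JAK/STAT signalling had 3 of 23 up and 0 down, namely Fadd Gene012594 (at least 2.77-fold) and the caspase Dredd at Gene004795 (at least 2.57-fold) and Gene004796 (2.38-fold). Apoptosis genes had 8 of 46 up and 4 down, with Buffy eGene18336 up 5.31-fold, programmed cell death 4a AK378765 up 4.08-fold and Apaf-1 Gene013082 up at least 1.84-fold. Autophagy genes had 2 of 12 up, Atg8 Gene006614 (2.64-fold) and the Atg4-like Gene014454 (2.32-fold). Small RNA machinery had 1 of 10 up and 1 down, and the member that fell, a Tudor nuclease at Gene000503, fell 4.13-fold.

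Heat shock proteins and chaperones had 30 of 107 members down and 5 up (33 and 7 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.000843, but adjusted p = 0.437 with an estimated correlation). Besides the small heat shock proteins, calreticulin Gene015220, a chaperone of the endoplasmic reticulum, fell 21.9-fold (-4.45, SE 0.32). Glycolysis and tricarboxylic acid cycle genes had 11 of 30 down and 3 up, with a median of -0.58 (adjusted p = 0.00567, but adjusted p = 0.437 with an estimated correlation). Pyruvate kinase Gene005206 fell 5.15-fold and pyruvate dehydrogenase Gene003686 fell 4.58-fold, while hexokinase Gene013196 rose at least 2.57-fold. Carbohydrate digestion and sugar transport had 17 of 65 down and 4 up (adjusted p = 0.0148, but adjusted p = 0.437 with an estimated correlation), with sugar transporter Gene016522 down at least 12.6-fold, Gene015337 down 8.12-fold and Gene015410 down 7.34-fold. Aminoacyl-tRNA synthetases had 7 of 24 down and 1 up (adjusted p = 0.0146, but adjusted p = 0.437 with an estimated correlation), for example glutaminyl-tRNA synthetase Gene007799, down 4.18-fold. Proteasome and ubiquitin genes had 28 of 112 down and 7 up (adjusted p = 0.0257, but adjusted p = 0.437 with an estimated correlation), with a proteasome beta subunit, Gene011402, down 7.28-fold and the ubiquitin-conjugating enzyme Gene002478 down 5.63-fold. Vacuolar ATPase genes had 7 of 32 down and 2 up (adjusted p = 0.0390, but adjusted p = 0.712 with an estimated correlation). Ecdysone and juvenile hormone genes had 11 of 64 down and 2 up (adjusted p = 0.0279, but adjusted p = 0.437 with an estimated correlation), with ecdysone oxidase Gene009866 down 7.01-fold and ecdysone 20-hydroxylase Gene003933 up at least 4.02-fold. The heat shock and glycolysis shifts held under all 8 other scalings tried. The hormone list missed the threshold under 7 of them and the hemocyte list under 6, and normexp with the percentile shift also ended those of the antimicrobial, sugar, aminoacyl-tRNA, proteasome and vacuolar ATPase lists.

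Transposable elements had 202 of 902 members up and 46 down (adjusted p = 0.00641, but adjusted p = 0.766 with an estimated correlation), and without repeated names the set no longer passed. Ribosomal proteins had 16 of 139 up and 2 down (adjusted p = 0.0392, but adjusted p = 0.959 with an estimated correlation), for example L34 eGene17408, up 6.12-fold, and this set shift no longer passed when arrays were scaled to the spike-ins (adjusted p = 0.627). The share of ribosomal proteins that rose was near that of all genes (2004 of 16104), and the share that fell was smaller (1527 of 16104). None of the other lists was shifted as a set by camera. The digestive protease list, defined by protease names, had 25 of 168 up and 22 down. Of its members 37 are named as inhibitors or as molting fluid enzymes, and without them 18 of 131 were up and 18 down, with a carboxypeptidase, Gene009734, up 8.88-fold. Serpins and other inhibitors had 13 of 58 up and 4 down (11 and 4 of 55 without 3 names of cDNA clones), with antitrypsin Gene016022 up 5.42-fold. Lipases had 7 of 42 up and 8 down, with sterol carrier protein Gene001581 down 5.35-fold. Detoxification enzymes had 8 of 140 up and 17 down, with cholinesterase 4A eGene21555 up 9.39-fold and CYP333B8 Gene004295 down 9.03-fold. Antioxidant genes had 0 of 34 up and 5 down by limma, with peroxiredoxin Gene016275 down 3.74-fold. Peritrophic matrix genes had 31 of 348 up and 10 down, with intestinal mucin eGene23727 down 12.3-fold. Cuticle proteins had 12 of 137 up and 8 down, mitochondrial respiration 11 of 108 up and 10 down (11 and 8 of 98 without vacuolar subunits), and DNA replication 8 of 89 up and 15 down, with proliferating cell nuclear antigen Gene012860 down 4.19-fold.

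Markers of other tissues in CSR-2 did not move as 1 block. Silk gland markers had 2 of 31 up and 2 down, with fibroin P25 eGene20049 up 6.70-fold and fibroin heavy chain Gene012180 down 4.47-fold. Fat body markers had 4 of 21 up and 1 down, or 3 of 16 up and 1 down without 5 fibrohexamerin genes that are also silk gland markers. The other lists were muscle markers 3 of 38 up and 7 down, Malpighian tubule and trachea candidate markers 3 of 14 up and 2 down, and neural markers 5 of 42 up and 4 down. In uninfected CSR-2 midgut only 8 silk gland, 9 fat body, 26 muscle, 10 Malpighian tubule and 20 neural markers were above background. Lipophorin receptor Gene002651 rose 6.80-fold and troponin T Gene007504 fell 3.96-fold. The 57 genes with virus names had 6 up and 1 down, or 4 of 34 up and 0 down without the names of other kinds. Of the 29 BmNPV genes, 3 rose in CSR-2: Bmnpvindiagp004 at least 7.63-fold, Bmnpvindiagp021 at least 4.26-fold and P6.9 at least 1.26-fold. Other probes of Bmnpvindiagp004 and Bmnpvindiagp021 did not rise. On the infected CSR-2 arrays 24 of the 29 were below background. Only 7 had a level in infected Sarupat larvae above the higher floor of the infected CSR-2 arrays (-5.82). Of these 5, among them 39K and the viral ubiquitin, were below background on both, with Sarupat levels from -5.76 to -4.88. The floor is the lowest signal called well above background, so a signal above it can still go undetected. The levels also come from different slides and scans, so these 5 genes do not show less viral signal in CSR-2.

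**Figure D2:**
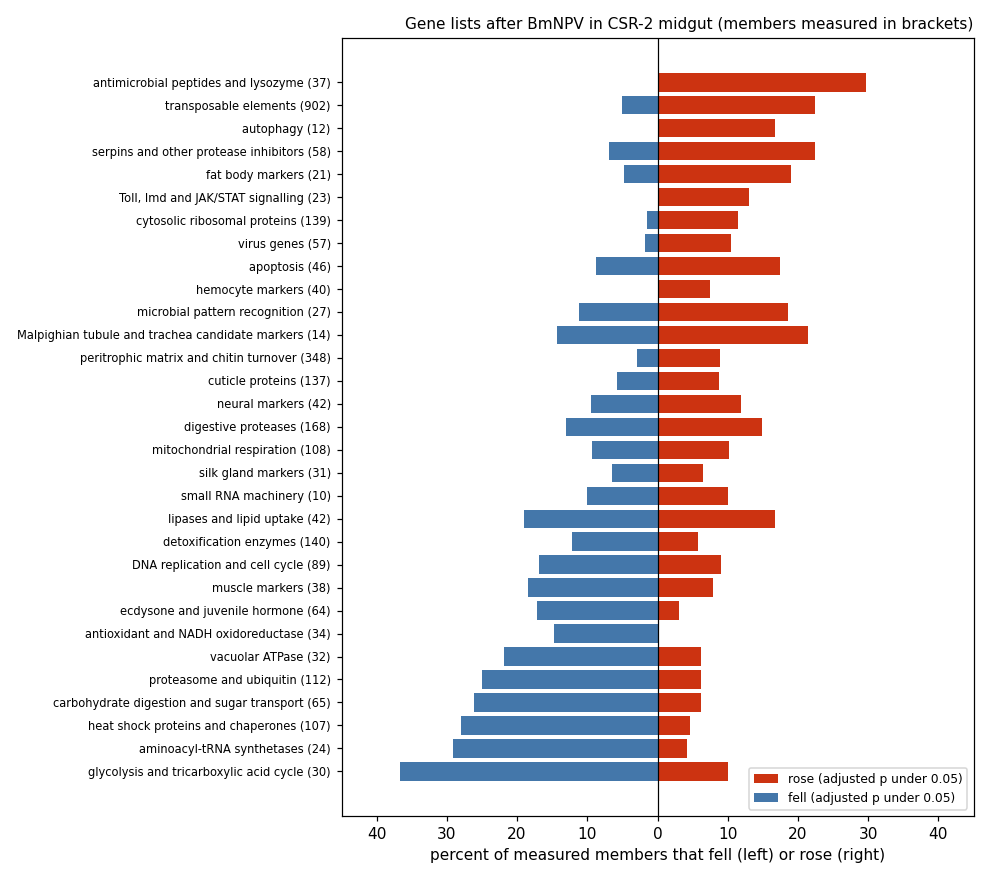
Percent of the measured members of each of the 31 gene lists that fell (blue, left) or rose (red, right) in CSR-2 midgut 12 h after BmNPV, by limma at an adjusted p under 0.05, with the members in brackets. Over all 16104 genes, 2004 rose and 1527 fell. Antimicrobial genes are at 1 end with 11 of 37 up and 0 down, and glycolysis and tricarboxylic acid cycle genes at the other with 11 of 30 down and 3 up; the percentages hold for the scaling to detected probes, and with spike-in scaling, which moved the median of all genes by -3.35, 0.247% of the changed genes rose.

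Uninfected and infected CSR-2 arrays were scanned separately at different detector voltages, so scan and infection cannot be told apart in this race. The count of 3531 was 5351 with 8 arrays counted as samples, 868 with the infected CSR-2 arrays also counted as 1 sample, and 1038 or 1037 without the first or second of those arrays. The share of changed genes that rose, 56.8%, was 47.5% with median centring, 44.8% with quantile normalization, 35.7% with the percentile over all probes, 43.4% with normexp and the percentile shift and 0.247% with spike-in scaling. These moved the median of all genes by -0.15, -0.05, -0.31, -0.43 and -3.35. On simulated arrays, 0 of 67 genes changed by a log2 of 1 were recovered, 43 of 67 changed by 2 and 66 of 66 changed by 4, with 8 unchanged genes called.

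The third comparison asked whether the races responded differently, as the difference between the 2 infection effects (Sarupat minus CSR-2). Sarupat arrays were scanned in 1 run and CSR-2 arrays in 2, uninfected and infected apart. A difference between the CSR-2 runs therefore enters every value of this comparison and cannot be told apart from a race difference in the response. It differed for 46 genes, 15 with a higher and 31 with a lower effect in Sarupat. The split was 12 higher and 2 lower with the percentile over all probes and with the deposited values, and 8096 higher and 503 lower with normexp and the percentile shift, which moved the median of all genes by 0.90. It was 1888 higher and 827 lower with 8 arrays as samples and the percentile over all probes. Of the 46 differences, 14 were measured above background on all arrays, 22 are bounds because an array was below background, and 10 have no size because the response of 1 race was not measured or no bound could be set. Gene015014 differed by 5.55 (log2, SE 0.48) and calreticulin Gene015220 by 4.27 (SE 0.50, adjusted p = 0.0448), both measured in both races. BTL-LP1 Gene009543 differed by -6.26 or lower (adjusted p = 0.0228). The retromer gene Gene011781 differed by at least 7.22 (log2, adjusted p = 0.0228), up in Sarupat and at -0.97 in CSR-2. The sugar transporter Gene016522 differed by at least 6.62, with a fold change of 2.96 (log2) in Sarupat that did not pass and the fall in CSR-2. In the other direction, the difference was -4.70 or lower for the retroelement eGene22373, whose other probe had 0.76, -3.30 or lower for the glutamate receptor Gene013178 and -3.51 or lower for the olfactory receptor Gene012905. The fitted differences of the last 2 were 0.48 and 0.59 with normexp and the percentile shift and did not pass (adjusted p = 0.313 and 0.213), against a median of all genes of 0.90. The glycoside hydrolase Gene011771, the endonuclease-reverse transcriptase eGene19075 and the proteasome ATPase Gene014827 passed too, but lay below background on all CSR-2 arrays, so their response in CSR-2 was not measured and no size is given. Attacin Gene003697 did not pass (-3.12 or lower, adjusted p = 0.0558). Of the antimicrobial list 1 of 37 passed, lower in Sarupat, and the set was lower in Sarupat (median -1.0, adjusted p = 0.00329, but adjusted p = 0.675 with an estimated correlation). Its median was 0.26 above that of other genes with normexp and the percentile shift and did not pass (adjusted p = 0.366). Hemocyte markers were lower with it (median -0.93, adjusted p = 0.0129, but adjusted p = 0.675 with an estimated correlation), and muscle markers higher (median 0.52, adjusted p = 0.0236, but adjusted p = 0.675 with an estimated correlation).

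Sugar transport genes responded higher in Sarupat (median 0.80, adjusted p = 0.00229, but adjusted p = 0.675 with an estimated correlation), with 1 of 65 members passing. Heat shock genes did too (median 0.20, adjusted p = 0.0236), as did glycolysis genes (0.56, adjusted p = 0.0219) and ecdysone and juvenile hormone genes (0.41, adjusted p = 0.0365), each with adjusted p = 0.675 with an estimated correlation. The glycolysis median relative to other genes was -0.24 with normexp and the percentile shift and did not pass (adjusted p = 0.873). Peritrophic matrix genes were higher (0.64, adjusted p = 0.00556) and transposable elements lower (-0.34, adjusted p = 0.0175), each with adjusted p = 0.745 with an estimated correlation. Relative to other genes the peritrophic median was -0.15 without cross-hybridising probes and -0.20 without repeated names, neither passing (adjusted p = 0.286 and 0.797). No size of a difference is given for the BmNPV genes, since 28 of the 29 were below background on both uninfected and 24 on both infected CSR-2 arrays. Bmnpvindiagp004 was nevertheless among the genes that differed, lower in Sarupat (fitted difference -4.37, SE 0.44). No bound could be set for it, and its other probes did not rise in CSR-2. Across the 16104 genes, which are not independent replicates, the 2 infection effects had a Pearson r of 0.0723 and a Spearman rho of 0.117, and 53.1% had the same sign. Among genes above background on all arrays (7269) r was 0.190 and rho 0.220. Of the 6 genes that fell in Sarupat, 1 also fell in CSR-2 (Hsp20.8, Gene015286), where chance gives 0.569 (Fisher's exact test, p = 0.450). Of the 9 that rose in Sarupat, 0 rose in CSR-2, where chance gives 1.12 (Fisher's exact test, p = 0.613). Of the genes that fell in Sarupat, Gene014827, eGene18433, Gene009798 and eGene19889 were below background on all CSR-2 arrays. So were Gene011771 and Gene009225 of those that rose, and a change in CSR-2 was not measured for any of them. The chance values treat these genes as measured, so these 2 tests cannot decide whether the responses overlap. For Hsp20.8 the 2 infected Sarupat arrays differed widely. With 8 arrays counted as samples, 2649 genes differed between the races. Of 37 antimicrobial genes, 10 had a lower and 1 a higher effect in Sarupat in that fit. In that fit 15 genes rose in both (chance 18.1, Fisher's exact test, p = 0.513) and 11 fell in both (chance 5.98, Fisher's exact test, p = 0.0419), among them both 90-kDa heat shock protein genes. The genes that fell in both are not all independent, since the probes of both 90-kDa heat shock protein genes are marked as cross-hybridising. Among these genes, ovS320B03f and fbS20691 were below background on all CSR-2 arrays, so a fall there was not measured. The fit also counts the infected Sarupat larvae as 2 samples. Of the genes that rose in Sarupat in it 33 fell in CSR-2, and of those that fell 5 rose. No chance value was computed for these opposite changes. The count of 46 was 0 without either uninfected CSR-2 array, 99 and 26 without the first and second uninfected Sarupat array, and 23 and 17 without the first and second infected CSR-2 array.

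The race comparisons asked which genes differed before and after infection. Race and slide cannot be told apart, since each race was on a slide of its own. In uninfected larvae 5343 genes differed, 3150 higher in Sarupat and 2193 higher in CSR-2, against 1748 and 4136 with the percentile over all probes. Of the 5343, 1643 are bounds and 665 have no fold. With a fold or bound, 2751 were higher in Sarupat and 1927 in CSR-2. Probes not above background had median signals of -11.37 and -11.03 on uninfected Sarupat and -8.04 and -7.26 on uninfected CSR-2 arrays. A gene undetected in CSR-2 can therefore be called lower in Sarupat without a fold, and the list counts can hold such genes. Bm122 Gene011647 was at least 884-fold higher in Sarupat (log2 12.06, SE 0.36), ferritin Gene013997, an iron store, at least 581-fold and peptidoglycan recognition protein B Gene009541, a sensor of bacterial cell walls, at least 250-fold. The vacuolar ATPase subunit AK383295 was at least 490-fold and a reverse transcriptase, eGene23621, at least 393-fold higher. The probes of these 2 are marked as cross-hybridising, and 11 and 284 measured identifiers carry their names. Another identifier of the same ATPase subunit, Gene016382, and another ferritin, Gene013998, were above background on all arrays of both races. The folds therefore hold for single probes and not for all genes of the name. Fungal protease inhibitor F was higher in CSR-2, at least 328-fold at AK382888 (log2 -10.18, SE 0.27) and at least 319-fold at fepMP01_F_H15. Both probes are marked as cross-hybridising too, and 8 measured identifiers carry this name, so the 2 values may not be independent. The cytosolic juvenile hormone binding protein NM_001044203.1 was at least 147-fold, an alcohol dehydrogenase, Gene005804, at least 181-fold and ME53 E_FL_mxg-_01P20_F_0 at least 230-fold higher in CSR-2. Of 139 ribosomal protein genes, 66 were lower and 6 higher in Sarupat (median -1.0, adjusted p = 5.85e-10, but adjusted p = 0.797 with an estimated correlation), for example L7A Gene008602 at -2.20. With normexp and the percentile shift, which moved the median of all genes by -2.29, their own median was -0.81, lower in Sarupat but above that of other genes by 1.5. Antimicrobial genes had 13 of 37 lower and 2 higher in Sarupat (adjusted p = 0.0240), glycolysis genes 7 of 30 lower and 1 higher (0.0261), vacuolar ATPase genes 8 of 32 lower and 1 higher (0.0436), the digestive protease list 49 of 168 lower and 26 higher (0.0488) and hormone genes 15 of 64 lower and 4 higher (0.0488). Each of these had adjusted p = 0.797 with an estimated correlation. Without inhibitors and molting fluid enzymes the protease list had 45 of 131 lower and 20 higher (0.00958, but adjusted p = 0.755 with an estimated correlation). With normexp and the percentile shift the own medians of the glycolysis (-0.63), vacuolar ATPase (-0.35) and digestive protease lists (-1.62) were also lower in Sarupat but above the median of other genes, past the threshold for the first 2 (adjusted p = 0.00422 and 9.87e-05) and not for proteases (0.0909). The vacuolar ATPase list had no shift past the threshold with normexp and quantile normalization (median 0.05) or with cyclic loess (0.19).

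In infected larvae 4239 genes differed, 2245 higher in Sarupat and 1994 higher in CSR-2. Here too some differences are bounds or have no fold because a group was below background, and the list counts can hold such genes. Gene011647, Gene013997 (at least 741-fold), AK383295 (at least 628-fold), Gene009541 (at least 334-fold) and eGene23621 (at least 338-fold) were again the named genes highest in Sarupat. Fungal protease inhibitor F (at least 1334-fold at fepMP01_F_H15), peritrophin type-A domain protein 1 Gene001038 (at least 662-fold), the chorion protein ERB4 Gene000847 (at least 126-fold) and an acyl-CoA oxidase, Gene005329 (at least 119-fold, SE 2.03), were higher in CSR-2. Antimicrobial genes had 18 of 37 lower and 1 higher in Sarupat (median -1.88, adjusted p = 3.02e-05, but adjusted p = 0.815 with an estimated correlation), with attacin Gene003697 39.7-fold and BTL-LP1 Gene009543 71.5-fold higher in CSR-2. Heat shock genes had 35 of 107 higher and 4 lower in Sarupat (median 0.61, adjusted p = 0.00629, but adjusted p = 0.815 with an estimated correlation), with hsp23.7 Gene015403 16.0-fold higher. Ribosomal proteins had 63 of 139 lower and 4 higher (median -1.21, adjusted p = 1.5e-11, but adjusted p = 0.815 with an estimated correlation). With normexp and the percentile shift, which moved the median of all genes by -1.58, their own median was -1.15 and the set no longer passed (adjusted p = 0.805). Peritrophic matrix genes had 110 of 348 higher and 36 lower (adjusted p = 0.0111, but adjusted p = 0.815 with an estimated correlation), a shift that no longer passed without cross-hybridising probes (adjusted p = 0.208). With spike-in scaling 96.5% of the changed genes were higher in Sarupat before and 99.5% after infection, against 59.0% and 53.0%, and with normexp and the percentile shift 5.69% and 7.24%. The count of 5343 was 1715 and 2168 without the first and second uninfected Sarupat array, and that of 4239 was 2344 and 2556 without the first and second infected CSR-2 array.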

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

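The infection effects of the races were compared by a planned test, and the test on neighbouring identifiers below was chosen only after the result was seen. Uninfected and infected CSR-2 arrays were scanned apart and Sarupat arrays together, so a difference between scans cannot be told apart from a race difference in the response. The difference between the effects passed for 46 genes, of which 10 are named here with fitted differences. Of the 46, 14 were measured on all arrays of both races, 22 are bounds and 10 have no size. Effects were higher in Sarupat for the retromer gene Gene011781 (8.97, log2), the glycoside hydrolase Gene011771 (7.88), the sugar transporter Gene016522 (7.37), the reverse transcriptase Gene015014 (5.55) and the endonuclease-reverse transcriptase eGene19075 (5.09). They were lower in Sarupat for the proteasome ATPase Gene014827 (-7.03), the reverse transcriptase-like gene eGene22373 (-6.80, though its other probe gave the opposite sign), BTL-LP1 Gene009543 (-6.44), the glutamate receptor Gene013178 (-5.49) and the olfactory receptor Gene012905 (-5.42). Only Gene015014 of these 10 was measured on all arrays of both races. Gene011781 (at least 7.22), Gene016522 (at least 6.62), eGene22373 (-4.70 or lower), Gene009543 (-6.26 or lower), Gene013178 (-3.30 or lower) and Gene012905 (-3.51 or lower) are bounds. With normexp and the percentile shift the fitted differences of Gene013178 and Gene012905 were 0.48 and 0.59 and did not pass, against a median of all genes of 0.90. Gene011771, eGene19075 and Gene014827 were below background on all CSR-2 arrays, so their fitted values measure no difference in size. As sets, 9 lists differed, with a median difference of -1.0 for antimicrobial genes, 0.20 for heat shock genes, 0.80 for sugar transport, 0.64 for peritrophic matrix, 0.41 for ecdysone and juvenile hormone, 0.56 for glycolysis, -0.34 for transposable elements, -0.93 for hemocyte markers and 0.52 for muscle markers. Relative to other genes the antimicrobial median was 0.26 and the glycolysis median -0.24 with normexp and the percentile shift. The peritrophic median was -0.15 without cross-hybridising probes and -0.20 without repeated names, and none of these 4 passed. None of the 9 differed with an estimated correlation (adjusted p = 0.675 or 0.745). The E1A spike-ins, used only for the alternative scaling to them, were 4.14 (log2) higher on infected than on uninfected CSR-2 arrays, while the 75th percentile of detected probes rose by 0.81. In Sarupat the same differences were 0.01 and -0.05.

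The large response in CSR-2 was weighed against technical causes, since its arrays were scanned in separate runs by infection. Over the 7269 genes above background on all arrays, a smooth curve on mean signal explained 2.49% of the variance of the CSR-2 fold changes, and one on probe GC content 3.40%. A surface over array position explained 0.0354%. Each lies under the 10% set beforehand as evidence against it as the main cause, for these genes only. Genes below background on any array were not covered, and 849 of the 3531 changes in CSR-2 are bounds and 413 have no fold. From uninfected to infected arrays the spike-ins rose by 4.14 (log2) and the 75th percentile of detected probes by 0.81. This gap was not part of these tests and stays open. A difference between the runs that affects genes one by one, the age or state of the uninfected larvae and the infection itself stay open, because run and infection coincide.

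The BmNPV signal in Sarupat, higher in 29 of 29 genes, was weighed against 2 causes. A scaling bias of dim genes was tested with 10000 random lists of larval genes with matched signal. Of these, 0 percent had as high a median, the highest being 0.55 against 1.66. The test cannot exclude such a bias, because the larval genes were not matched on how they passed the filter. Of the BmNPV genes 28 were above background on both infected and 17 on both uninfected Sarupat arrays. Without that filter, and with normexp and quantile normalization, the BmNPV median was lower. Larval RNA bound by the virus probes would dilute the rise in genes with high uninfected signal. The rank correlation of fold change with uninfected level was -0.278 (permutation p = 0.144), between the bounds set beforehand for and against that cause, so binding of larval RNA cannot be told apart from viral transcripts in the uninfected signal. Virus transcripts at 12 h, a carried-over infection in the uninfected larvae, and differences between larvae stay open.

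Genes measured in 1 Sarupat group and below background in the other were weighed as a possible difference in genotype between the groups. By this rule, with a signal at least 2-fold lower in the group below background, 60 genes were higher and 63 lower in infected larvae. With limma 13 of them passed and 110 did not. The test on neighbours took only the 74 whose identifier is Gene and a number (32 higher and 42 lower, 8 passing) and left out the other 49. Of the 74, 11 had another such gene within 10 identifier numbers, against a median of 6 and a 95th percentile of 12 in 10000 draws of genes of like signal (8.88% of the draws gave as many). The stretch from Gene011771 to Gene011781 holds 3 of them, with the glycoside hydrolase and the retromer gene at its ends. Of the 8 among these 74 that passed, 2 had another within 10 numbers (a count reached in 3.35% of matched draws), a test made after the values were seen. A difference in genotype, a response to infection and differences between larvae stay open with 1 infected sample.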

How the results depend on the processing

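Most named genes kept their direction and side of the threshold over the alternatives: 539 of the tests of named genes in CSR-2 held and 21 fell short, 276 held for uninfected races, 271 held and 5 fell short for infected races, 198 held, 61 fell short and 2 reversed for the difference between effects, and 204 held, 100 fell short and 3 reversed in Sarupat. The counts below are of changed genes; the cause of each change was not tested, except where fewer genes or samples were used. Against 15 in Sarupat, 3531 in CSR-2, 46 for the difference, 5343 for uninfected and 4239 for infected races, counts beyond 1.5 times follow, where values with no comparison named are for Sarupat and then CSR-2, or for all 5 in that order. Median centring gave 23 for the difference, quantile normalization 1 in Sarupat and 386 for the difference. Normexp with the 75th percentile gave 5717, 1733, 8599, 13608 and 12606 in that order, and moved the median of all genes by 0.48, -0.43, 0.90, -2.29 and -1.58. Under it the signs changed of eGene18433 (0.051), Gene009798 (0.14) and eGene19889 (0.43) in Sarupat and Gene013178 (0.48) and Gene012905 (0.59) for the difference, all below that median and none past the threshold. Relative to other genes, so did those of the cuticle list (0.14) in Sarupat, the antimicrobial (0.26) and glycolysis (-0.24) lists for the difference, the digestive protease (0.68), ribosomal (1.5), glycolysis (1.66) and vacuolar ATPase (1.95) lists for uninfected and the ribosomal list (0.44) for infected races. Of these only the ribosomal, glycolysis and vacuolar ATPase lists for uninfected races passed, and the race lists' own medians stayed lower in Sarupat. The correlation of the effects was -0.101 against 0.0723. Normexp with quantile normalization gave 0 in Sarupat, 1214 for the difference, a correlation of 0.179 and a vacuolar ATPase difference of 0.017 in uninfected races, which did not pass. No filter on dim probes gave 24, 2166, 17140 (uninfected) and 15487 (infected races), and only probes above background on all 8 arrays gave 2, 611 (difference), 3438 (uninfected), 2765 (infected races) and a correlation of 0.190. Each probe tested gave 23 and 174 (difference). A replicate block on 8 arrays gave 85, 2229 (difference) and 7652 (infected races). The replicate numbers appear only shared, not paired: deviations of replicate 1 from 2 correlated between groups from -0.0662 to 0.208 over probes.

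Trend and robust variances gave 33 and 912 (difference), and no moderation 0, 1272, 6, 1241 and 901. A fold of 2 in every pair of arrays with no p gave 521, 2177 (difference) and 3407 (uninfected races). Only the arrays compared gave 0 in Sarupat and cannot give a value for the difference. Array weights gave 25, 2115, 11, 2672 and 6535, and the deposited log2 values gave 6 and 14 (difference). As first planned, 8 arrays as samples gave 138, 5351, 2649 (difference) and 7755 (infected races), the percentile over all probes 6 and 14 (difference), and both together 107, 2715 (difference) and 7493 (infected races). Chosen after the data were seen, 6 samples gave 868 in CSR-2, 16 (difference) and 2303 (infected races). Spike-in scaling gave 24, 15393, 13250 (difference) and 15600 (infected races) and moved the median of all genes in CSR-2 by -3.35. It ended the call of ribosomal proteins in CSR-2 (adjusted p = 0.627), whose median stayed 0.35 above other genes while the set test's direction was down. Cyclic loess gave 31 and 394 (difference), with vacuolar ATPase in uninfected races at 0.19 and not passing. Without cross-hybridising probes infected races gave 2635, and peritrophic genes lay lower than other genes for the difference (-0.15) and infected races (-0.19), as they did without repeated names (-0.059 in Sarupat, -0.20 for the difference, 0.027 by the median but down by the set test in infected races), none of these past the threshold. Without list members of another kind the list of virus names, 29 of the 34 left being BmNPV genes, passed for the difference (adjusted p = 0.000296 against 0.0995, up) and for uninfected races (0.00997 against 0.257, down), while most BmNPV genes were below background in CSR-2. No other list changed side of the threshold. Leaving out 1 array gave 0 to 49 in Sarupat (0 without either uninfected CSR-2 array, 49 and 28 without the first and second uninfected Sarupat array), 1037 to 4092 in CSR-2 (1038 and 1037 without the first and second infected array), 0 to 99 for the difference (0 without either uninfected CSR-2 array, 99 and 26 without the first and second uninfected Sarupat, 23 and 17 without the first and second infected CSR-2 array), 1715 to 7312 for uninfected races (1715 and 2168 without the first and second uninfected Sarupat, 3527 without the second uninfected CSR-2 array), 2344 to 6044 for infected races (2344 and 2556 without the first and second infected CSR-2 array), 1.54 to 1.86 for the BmNPV median in Sarupat, and 0.00777 to 0.116 for the correlation (0.00777 and 0.116 without the first and second uninfected Sarupat array). Over the other alternatives that gave a BmNPV median it ran from 0.11 (normexp with quantile normalization) to 1.76 (median centring), with 0.70 without a filter on dim probes (16 of 69 genes negative), 1.13 with normexp and the percentile, and 1.18 with quantile normalization. It was not computed for only probes above background on all arrays, each probe tested, fold thresholds, genes above background in a compared group, repeated names or names of another kind. On CSR-2 arrays, 7603 (uninfected) and 9196 (infected) of 16104 genes were above background on both arrays, against 15179 and 15580 in Sarupat, which limits falls and low levels there to bounds.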

Other observations

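ME53, a product name taken from an early baculovirus gene, was chosen here after its values were seen. The identifier E_FL_mxg-_01P20_F_0 with this name was below background on all Sarupat arrays and above it on all CSR-2 arrays. Its level in CSR-2 was -1.51 (log2, SD 0.42) in uninfected and -3.67 (SD 0.16) in infected larvae, and it fell 4.48-fold with infection (log2 fold change -2.16, SE 0.31, adjusted p = 0.00809 by limma). Of 6 identifiers with this name, ceN-0784 and wv40097 were above background in both races and did not pass between uninfected races (log2 differences of 0.79 and 0.64). The name therefore says nothing firm on whether a probe reads virus or larval RNA.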
